A study of Mus musculus with 6 samples.

How the data were processed

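RNA from mouse CD4+ T cells was measured by sequencing in 6 libraries, 3 from cultures with desIgf1 and 3 from control cultures without it. desIgf1 is a truncated insulin-like growth factor 1 that binds IGF-binding proteins poorly. Per the labels' protocols, naive CD4+ T cells of C57BL/6 mice carrying reporters for Il17a (human CD2), Ifng (Thy1.1) and Foxp3 (GFP) were cultured for 5 days with soluble anti-CD3 (5 µg/mL), irradiated splenocytes depleted of CD4+ cells, IL-6 (20 ng/mL), TGF-β (2.5 ng/mL) and antibodies against IFN-γ (10 µg/mL) and IL-4 (10 µg/mL). desIgf1 was used at 30 ng/mL. The cells sorted for RNA carried the Il17a reporter and lacked the other reporters, and libraries were made with a stranded mRNA kit. The protocol text lists desIgf1 for all 6 libraries, while the series design and the sample titles separate cultures with and without it. The groups follow the titles and descriptions.

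The deposited values are whole-number counts per gene, not normalized, and the labels name no separate normalization for them. Per the submitters' processing notes, the tools were Trim Galore 0.4.5, STAR 2.5.3, SAMtools 0.1.18, HTSeq 0.7.2, DESeq2 1.18.1 and R 3.4.3, with the mouse build GRCm38 (mm10). The notes give no role or settings for them. The annotation release and the strand setting of the counting are not given in the sources used here, so antisense and overlapping genes are uncertain. Each file held 39179 genes and 5 summary lines that name no gene. Those lines stayed out of library sizes and tests. Among uniquely placed reads, 13.5 to 15.7% overlapped no gene and 0.712 to 0.761% were ambiguous. Alignments marked as not unique made up 46.4 to 48.7% of all entries, and they are not in the gene counts, which lowers the values of genes with near-identical copies. Gene symbols, biotypes and coordinates came from GENCODE M21 (GRCm38), which matched 37693 of the gene identifiers.

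Gene counts summed to 40081675, 42441076 and 47929948 in desIgf1 libraries 1 to 3 and to 45874707, 42860119 and 34567899 in control libraries 1 to 3. The most abundant gene, Eef2, took 0.475 to 0.563% of the counts. No libraries of one group were copies of each other, since the chi-square per degree of freedom between them was 41.0 to 132. The labels do not say whether libraries came from separate cultures or animals, so p-values measure the spread between these libraries.

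Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with a minimum count of 10, robust quasi-likelihood fit and test, group as the only term). The filter left 13846 genes. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and the threshold was 0.05. CPM are values of edgeR's cpm function with TMM factors, given as mean ± SD with n = 3. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg values over 30 lists of at least 5 tested genes. The lists, markers, tests, groups, named-gene rule and most alternatives were fixed before the data were examined. Marker lists of other cell types were compared as summed CPM with a two-sided exact permutation test, which cannot go below 0.1 with 3 libraries against 3. The test of RNA from splenocytes took 3 forms, each after values were seen, namely the median of pooled markers, medians by cell type, and the level of abundant transcripts that added cells could hold. The last is used, with 0.1% of the RNA of a cell as the least level of an abundant transcript, a value that was assumed. By the medians alone dendritic cells and macrophages stay open, and the last form does not settle them either. Tyrobp and Fcer1g were added to the abundant macrophage transcripts after a run with Lyz2 and Ctss alone had left macrophages open.

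Titles number the libraries 1 to 3 in both groups. The deviations of same-numbered libraries from their group means correlated at 0.59, 0.32 and 0.55 for numbers 1, 2 and 3, across genes, and at 0.51, 0.29 and 0.55 without genes of the X and Y chromosomes. Both number 1 libraries held Xist and almost no Y-linked counts, and both libraries of numbers 2 and 3 held the reverse. The numbers were therefore treated as pairs, from the data and not from a label, and values of a fit with the replicate number as a block are given beside the results that this fit changed (44 genes called against 0). That fit has 2 residual degrees of freedom, against 4 without the block. Camera with an estimated in place of the preset correlation uses these degrees of freedom. A list call lost there need not be lost to correlation between genes.

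The rule for named genes took genes fixed beforehand, among them Il17a, Ifng, Foxp3 and Igf1r; up to 8 genes in each direction with the largest change among those past the threshold, or the smallest p where fewer passed, at a mean of at least 1 CPM, with a symbol that is not a predicted gene, a pseudogene or a Riken name and no overlap between the groups; up to 4 members of each list past a test and its first tested gene; and the 3 smallest p-values. The same rule was applied to the blocked fit, with the same direction in all 3 pairs in place of no overlap, and the 3 smallest p-values of each list were added, after the data were examined.

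Alternatives were median-of-ratios and upper-quartile factors, no low-count filter, a filter of at least 50 counts in each of 3 libraries, DESeq2 1.42.0, limma voom, protein-coding genes only, each library left out in turn, and for lists an estimated correlation and fry. Chosen after the data were examined were combinations of the block with these tools and filters, with a correction for GC content and gene length (loess span 0.5, values for 98.9% of tested genes), with libraries thinned to the smallest total, and with both libraries of one number left out.

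The tests were tried on 5 simulated data sets per fit, with 13846 genes drawn from the means and library sizes of this comparison and 200 genes changed. edgeR without the block recovered 58.5% of the 2-fold changes and 87.8% of the 4-fold changes, and 7.98% of its calls were false. With the block it recovered 84.8% and 98.2%, with 10.9% of its calls false. The data for the blocked fits were drawn with the pairs as real and with the dispersions of the blocked fit. Shares with and without the block thus come from different simulated data. They do not show the false calls of the block if the numbers are not pairs. DESeq2 without the block recovered 76.1% and 95.5%, and 27.3% of its calls were false. Of 1.5-fold changes, edgeR recovered 8.79% without the block and 46.4% with it, and its estimate had the wrong direction for 10 and 3 of 330 such genes. Camera found a list shifted by 0.5 on the log2 scale in all 5 simulations of each fit. It also called 2 other lists over the simulations without the block and 0 over those with it. Genes were drawn independently of each other, while the estimated correlation was 0.42 for cholesterol synthesis and 0.87 for S phase genes. The simulations therefore do not test the preset correlation of camera. Plots were drawn with matplotlib 3.10.9.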

Results

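Gene expression was measured in Th17 cells that had been generated in culture with or without desIgf1, to ask how signalling through the insulin-like growth factor receptor changes what these cells express. The cells were sorted on day 5 for expression of the Il17a reporter and for absence of the Ifng and Foxp3 reporters. The design gives 1 comparison, 3 libraries with 30 ng/mL desIgf1 against 3 control libraries, with 34567899 to 47929948 counts in genes per library. On the first principal component of log2 CPM, with 43.5% of the variance, both number 3 libraries stood apart from the other 4, and on the second, with 27.0%, all 3 desIgf1 libraries lay above all 3 controls.

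**Figure D1:**
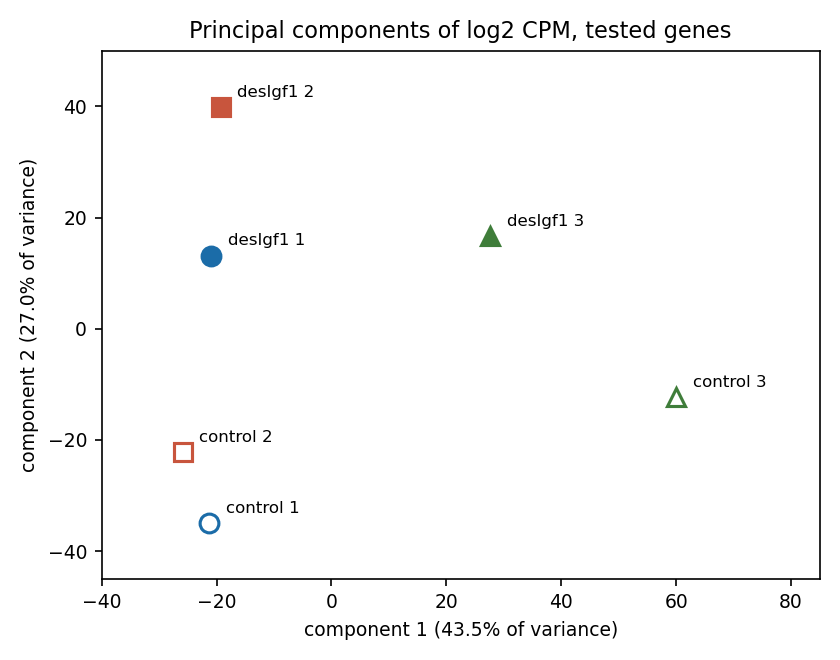
First and second principal components of log2 CPM over the 13846 tested genes, with 1 point per library, filled for desIgf1 and open for control, and shape and colour for the replicate number. The number 3 libraries lie at 27.57 and 59.98 on component 1, and the other 4 lie between -25.92 and -19.31.

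Single genes of glycolysis, of the response to low oxygen, of cholesterol synthesis and of chemokine reception were higher with desIgf1 in each of the 3 replicate numbers, and the naive T cell gene Klf2 was lower in each. With the replicate number as a block, Aldoc (aldolase C, a glycolytic enzyme) rose 3.38-fold, Slc2a3 (the glucose transporter GLUT3) rose 2.61-fold, Hmgcs1 (an early enzyme of the mevalonate pathway) rose 2.08-fold and Ccr2 (a chemokine receptor) rose 4.03-fold. Klf2, a transcription factor that drives lymphocyte recirculation, fell by 1.38 on the log2 scale. In edgeR's quasi-likelihood test without the block, 0 of 13846 genes passed an adjusted p of 0.05, with 1130 genes at an unadjusted p under 0.05 where chance gives 692. limma voom also called 0 genes, and DESeq2 called 202, 111 higher and 91 lower. With the block, edgeR called 44 genes, 25 higher and 19 lower, all 44 in the same direction in all 3 pairs, and 37 of them changed at least 2-fold. The blocked test selects for a small spread between pairs, so this agreement is no separate support.

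The 44 genes rest on the block. Without the libraries numbered 1, 2 or 3 the blocked fit called 72, 620 or 1069 genes, with fewer residual degrees of freedom, and 34, 44 and 44 of the 44 were among them. Those fits reuse the same libraries, so the overlap is no independent support. A correction for GC content and gene length left 11, while the median absolute log2 fold change of the 44 went from 1.38 to 1.37 and their adjusted p-values were at most 0.124.

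Of the 44 genes, Cables1 rose most among those at 1 CPM or more, 5.40-fold (log2 2.43 ± 0.27 SE, edgeR adjusted p = 0.0467), from 0.583 ± 0.216 CPM (SD, n = 3) to 3.21 ± 1.31. Adgrg5, an adhesion G protein-coupled receptor, rose 5.37-fold (adjusted p = 0.0179), from 8.41 ± 2.98 to 45.1 ± 14.2 CPM. Cd93 rose 5.25-fold (adjusted p = 0.0467) and Plcxd1 rose 3.11-fold (adjusted p = 0.0332). Gpr65, a proton-sensing receptor on chromosome 12 (98268635 to 98276644), rose from 25.0 ± 1.95 to 80.3 ± 17.8 CPM. Its log2 fold change was 1.66 ± 0.12 with the block (adjusted p = 0.0226) and 1.68 ± 0.17 without it (adjusted p = 0.112). Pygl, a glycogen phosphorylase, rose 3.52-fold (adjusted p = 0.0245).

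Among the 44 genes, the largest fall at 1 CPM or more was in Rbpms2, an RNA-binding protein gene on chromosome 9 (65629648 to 65660528). It was at 311, 276 and 31.2 CPM in controls 1 to 3 and at 24.8, 21.6 and 4.44 CPM in desIgf1 libraries 1 to 3, and fell by 3.41 ± 0.20 on the log2 scale with the block (adjusted p = 0.0112). Without the block its adjusted p was 0.435, since both number 3 libraries were far lower than the rest of their group. Clstn3 fell by 2.27, Iglon5 by 2.11, Cd33 by 1.74, Qrfp by 1.61, Col4a1 (a basement membrane collagen chain) by 1.60 and Rin2 by 1.43 on the log2 scale, with blocked adjusted p-values from 0.0103 to 0.0496. The predicted gene Gm14085, among the 3 smallest blocked p-values, fell by 2.83 (adjusted p = 0.0103).

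Several genes stood apart in every library without passing either edgeR test, and Trio did so while passing only with the block. Slamf6, a receptor of the SLAM family, was at 363 ± 43.0 CPM in controls and 158 ± 20.4 with desIgf1, a log2 fold change of -1.20 ± 0.14 (adjusted p = 0.112, and 0.0512 with the block). Il6ra, the IL-6 receptor, was at 193 ± 7.71 and 117 ± 9.40 CPM (log2 -0.72, adjusted p = 0.112, blocked 0.0577). Cd40lg, the CD40 ligand, was at 49.6 ± 2.22 and 87.9 ± 12.9 CPM (log2 0.82, adjusted p = 0.170, blocked 0.0633). Gcnt2, AW112010, Padi2 and Cd24a were higher with desIgf1 and Zfyve28 and Cd55 lower, with adjusted p-values of 0.112 to 0.170 without the block and 0.0511 to 0.0699 with it. Trio was at 64.8 ± 10.0 and 32.6 ± 1.19 CPM, not past the test without the block (adjusted p = 0.112), and fell by 0.98 with it (adjusted p = 0.0443). Over all genes, 1867 (13.5%) had all 3 libraries of one group above all 3 of the other, where chance gives 10%.

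**Figure D2:**
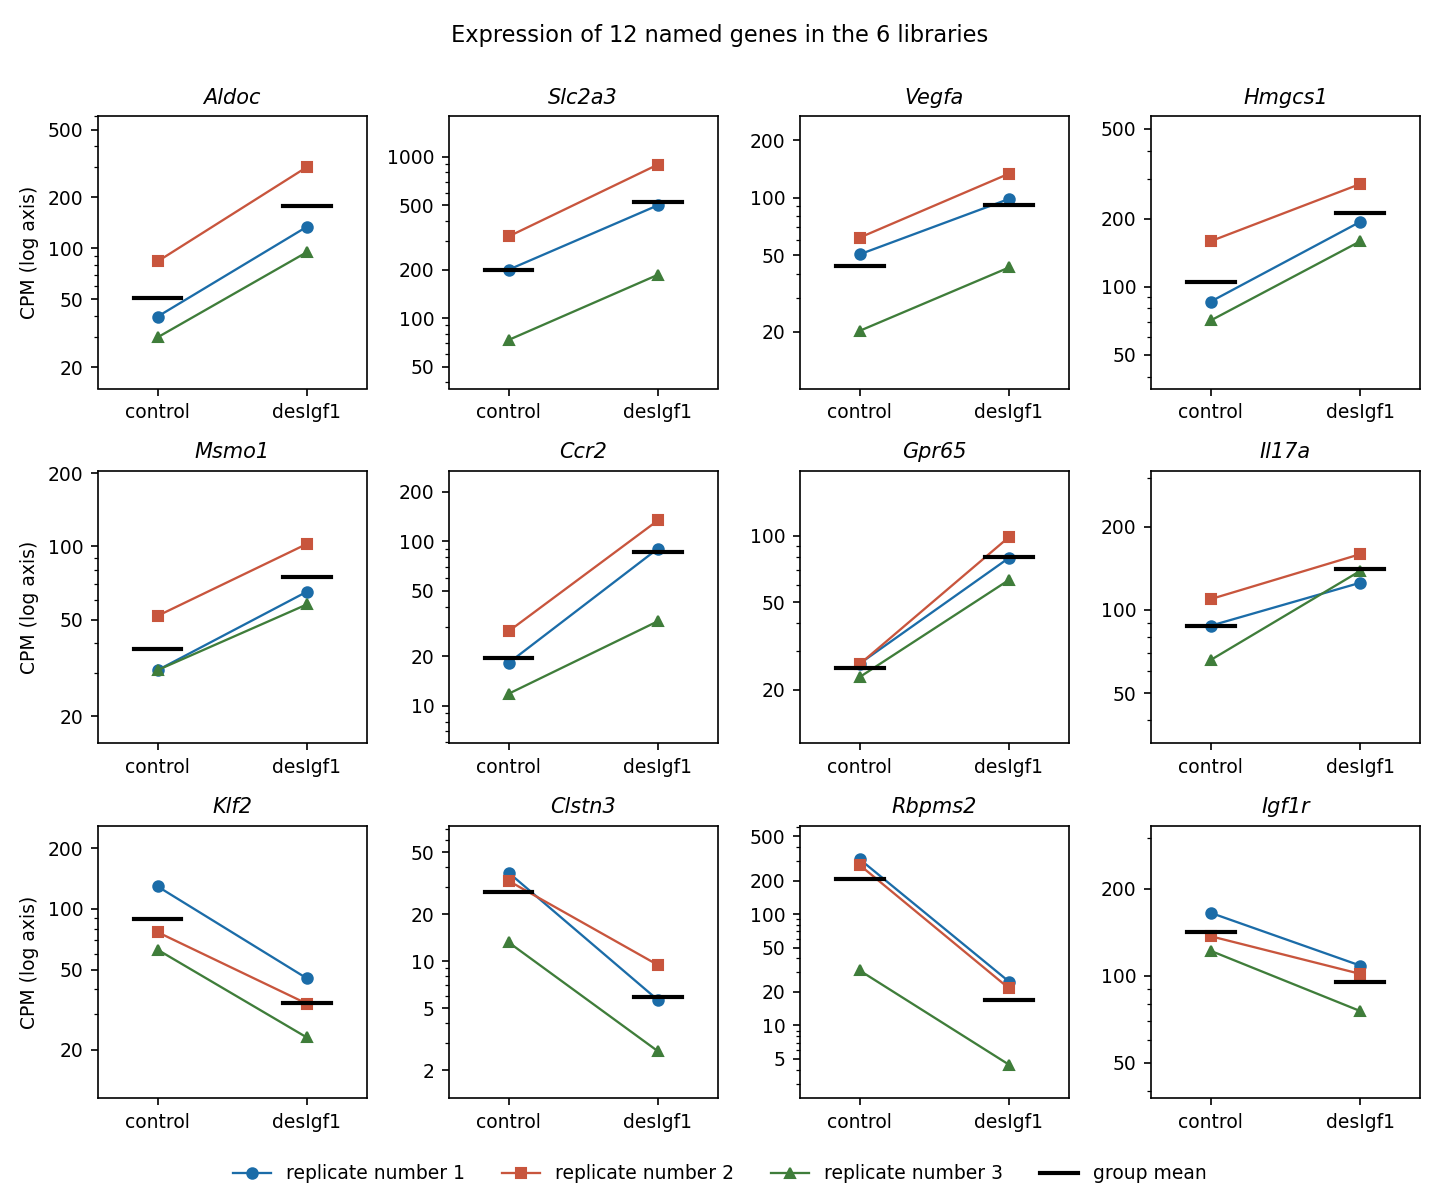
CPM of 12 genes in the 6 libraries on log axes, with a line joining the control and desIgf1 library of each replicate number and a black bar at the group mean. Aldoc goes from 51.1 to 177 CPM in the group means and Rbpms2 from 206 to 16.9, each with the same direction in all 3 pairs.

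The sort was on Il17a, and its transcript was present in all libraries. Il17a (chromosome 1, 20730905 to 20734496) was at 125, 159 and 138 CPM with desIgf1 and at 87.7, 109 and 66.0 CPM in controls 1 to 3. The log2 fold change was 0.68 ± 0.19 and did not pass (edgeR adjusted p = 0.441, and 0.124 with the block). Ifng had 1 to 28 counts per library and was too low to test. Foxp3 was at 0.237 to 1.80 CPM, highest in both number 3 libraries, with an adjusted p of 0.982. As genes of the sort gate, these values check the sort and are no separate finding.

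Of the Th17 programme, 32 genes were tested and 0 passed over all genes, with or without the block. Adjusted over the list alone, 5 were higher and 3 lower without the block and 10 were higher and 5 lower with it. The list as a whole did not pass camera (adjusted p = 0.452), but passed the mixed fry test, which asks for change in either direction (adjusted p = 0.00197, and 0.0217 with the block). Il17f was at 670 ± 152 CPM in controls and 1022 ± 101 with desIgf1 (log2 0.61 ± 0.17, adjusted p = 0.452), Rbpj at 111 ± 25.3 and 178 ± 31.7 CPM (log2 0.68 ± 0.19, adjusted p = 0.452) and Rora at 325 ± 21.6 and 486 ± 113 CPM (log2 0.58 ± 0.17, adjusted p = 0.455). Il17f, Rbpj and Rora were named after their values were seen. The pathogenic Th17 signature had a median log2 fold change of 0.20 and did not pass camera (adjusted p = 0.119), but passed the mixed fry test (0.0328, and 0.00443 with the block). The Treg programme (camera adjusted p = 0.376) did not pass, nor did Th2 genes (0.978) or exhaustion and co-inhibition genes (0.974).

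Cholesterol synthesis was the list with the smallest p. In camera with the preset correlation it was higher with desIgf1 (median log2 fold change 0.52 over 28 genes, adjusted p = 5.04e-10), but adjusted p = 0.732 with an estimated correlation. Of its genes, 4 rose with the block and 24 did not pass. The 4 were Hmgcs1 (log2 1.06 ± 0.10, adjusted p = 0.0390), Msmo1 (0.99 ± 0.09, 0.0332), Hsd17b7 (0.98 ± 0.09, 0.0332) and Mvd (0.91 ± 0.10, 0.0475), enzymes of the mevalonate and sterol branches. Without the block 0 passed. Adjusted over the list alone, 19 were higher with the block and 0 without it, and 21 of the 28 were higher in all 3 pairs. Acat2, the first gene of the list, was at 23.2 ± 10.6 and 28.3 ± 4.91 CPM (adjusted p = 0.820). Fatty acid synthesis genes were also higher in camera (median 0.24 over 20 genes, adjusted p = 0.00398), but adjusted p = 0.732 with an estimated correlation, and 0 passed over all genes. Without control library 3 the median was 0.13 and the call ended (adjusted p = 0.385), as it did with the block without the libraries numbered 3 (0.16, adjusted p = 0.152). With adjustment over that list alone, 4 were higher with the block and 0 without it. Scd1, a stearoyl-CoA desaturase, was at 35.2 ± 39.6 CPM in controls and 163 ± 42.2 with desIgf1, and Scd2 at 768 ± 401 and 1658 ± 277 CPM, with blocked adjusted p-values of 0.0976 and 0.0835. Lpin1 was at 49.5 ± 8.91 and 85.5 ± 21.2 CPM (blocked 0.0633), and Acly at 460 ± 50.4 and 510 ± 26.4 CPM (blocked 0.483).

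The hypoxia response and glycolysis were higher in camera as well. For 25 hypoxia genes other than those of glycolysis the median log2 fold change was 0.31 (adjusted p = 3.15e-04), but adjusted p = 0.732 with an estimated correlation. For 27 glycolysis genes it was 0.13 (adjusted p = 0.0102), but adjusted p = 0.755 with an estimated correlation. Both calls ended without control library 3, with medians of 0.17 and 0.01 (adjusted p = 0.156 and 0.958), and that of glycolysis also in the blocked fit without the libraries numbered 3 (0.12, adjusted p = 0.175). Vegfa, the vascular growth factor, rose by 1.06 ± 0.09 (adjusted p = 0.0332) and Ero1l, an oxidoreductase of the endoplasmic reticulum, by 0.84 ± 0.09 (adjusted p = 0.0443) with the block. Ndrg1 was at 92.6 ± 51.1 and 226 ± 161 CPM (blocked adjusted p = 0.0512). Aldoc (chromosome 11, 78322968 to 78327781) rose by 1.76 ± 0.09 (adjusted p = 0.0103) and Slc2a3 (chromosome 6, 122727809 to 122801640) by 1.38 ± 0.09 (adjusted p = 0.0136) with the block. Pdk1 (blocked adjusted p = 0.114) and the other glucose transporter gene Slc2a1, at 206 ± 79.4 and 208 ± 33.3 CPM, did not pass. Adjusted over the list alone, 13 hypoxia genes and 6 glycolysis genes were higher with the block and 0 of either without it.

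Of 22 chemokine and chemokine receptor genes, 3 rose with the block, among them Ccr2 by 2.01 ± 0.19 (adjusted p = 0.0332) and Ccl22 by 1.58 ± 0.18 (adjusted p = 0.0496). The list was higher in camera (median log2 fold change 0.49, adjusted p = 3.93e-04), but adjusted p = 0.366 with an estimated correlation. That correlation was -0.025, below the preset 0.01, so the call was not lost to a higher correlation. The directional fry test gave an adjusted p of 0.0165 without the block and 0.105 with it. Adjusted over the list alone, 8 were higher and 1 lower with the block and 0 without it. Dendritic cell markers, Ccl22 among them, summed to 218 ± 40.8 CPM with desIgf1 and 158 ± 21.3 CPM in controls. Ccl3, the first of the list, was at 6.19 ± 4.52 and 7.13 ± 5.48 CPM. The Th1 and cytotoxic list did not pass (camera adjusted p = 0.313). In that list Tnf and Il18rap had blocked adjusted p-values of 0.0512 and 0.0577, and Tbx21, the gene of T-bet, was at 1.34 ± 0.651 and 0.682 ± 0.397 CPM. The TGF-β target list did not pass (camera adjusted p = 0.828), and its genes Serpine2, Pmepa1 and Smad7 did not either. P2rx7, an ATP-gated channel, was the only called gene of the Tfh list, rising by 0.88 ± 0.10 (blocked adjusted p = 0.0467), while the list did not pass (0.828) and Bcl6 was at 89.4 ± 36.6 and 115 ± 7.58 CPM.

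Naive and memory T cell genes were lower in camera (median log2 fold change -0.21 over 20 genes, adjusted p = 0.0119), but adjusted p = 0.732 with an estimated correlation. The call also ended without control library 1 (median -0.05, adjusted p = 0.0910) or desIgf1 library 3 (-0.08, 0.358), and with the block without the libraries numbered 1 (-0.03, 0.0809) or 3 (-0.14, 0.127). Of its genes 2 fell with the block, among them Klf2 (chromosome 8, 72319033 to 72321656), by 1.38 ± 0.11 (adjusted p = 0.0245). Klf2 went from 89.7 ± 35.1 to 34.1 ± 11.1 CPM. Adjusted over the list alone, 4 were lower without the block, and 6 lower and 1 higher with it. Actn1 was at 142 ± 44.7 and 78.2 ± 8.37 CPM (blocked adjusted p = 0.124). The list's median difference was -0.41 and -0.48 in numbers 1 and 3 and 0.12 in number 2. Klf2 is also a member of the FOXO target list, which did not pass camera (adjusted p = 0.0753), and in which Klf3 had a blocked adjusted p of 0.0669. The adhesion and trafficking list did not pass (camera adjusted p = 0.532). In it Itga3 and Cd44 did not pass (blocked adjusted p = 0.0943 and 0.119) and Itga2 was below 3 CPM in both group means, at 2.93 and 2.44.

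Genes of the IGF and insulin pathway did not pass camera without the block (median log2 fold change -0.13 over 26 genes, adjusted p = 0.0507) and were lower with it (adjusted p = 0.0321), but adjusted p = 0.813 with the block and an estimated correlation. Of its genes 0 passed over all genes, and adjusted over the list alone 1 was higher and 1 lower with the block and 0 without it. Igf1r, the receptor of desIgf1 (chromosome 7, 67952827 to 68233668), was at 141 ± 21.8 CPM in controls and 95.2 ± 17.3 with desIgf1, with no overlap between the groups. Its log2 fold change was -0.57 ± 0.17 (adjusted p = 0.483) and did not pass with the block either (-0.57 ± 0.09, adjusted p = 0.0838).

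Cell cycle and ribosome biogenesis genes were lower in camera, but the pairs differed. S phase genes had a median log2 fold change of -0.35 over 51 genes (adjusted p = 6.01e-09), but adjusted p = 0.732 with an estimated correlation. Their median difference was -0.18, -1.06 and 0.24 in numbers 1, 2 and 3. For 55 G2 and M phase genes the median was -0.26 (adjusted p = 1.35e-06), but adjusted p = 0.755 with an estimated correlation, and the 3 pairs gave -0.03, -0.95 and 0.18. Without control library 2 the median was -0.04 and the call ended (adjusted p = 0.425). For 44 ribosome biogenesis and MYC target genes it was -0.32 (adjusted p = 1.24e-08), but adjusted p = 0.732 with an estimated correlation, and the pairs gave -0.39, -0.75 and 0.20. With the block and without the libraries numbered 2 all 3 calls ended, with medians of -0.00219, 0.0773 and -0.10 (adjusted p = 0.855, 0.175 and 0.186). In these 3 lists 0 genes passed over all genes or adjusted over the list alone, with or without the block. Mcm2, a subunit of the replicative helicase, was at 335 ± 74.9 and 237 ± 51.3 CPM (adjusted p = 0.608), Myc at 187 ± 46.5 and 147 ± 27.2 CPM (adjusted p = 0.661) and Hmgb2 at 52.1 ± 15.9 and 47.8 ± 10.4 CPM (adjusted p = 0.896). Mcm7, Cdt1, Psrc1, Cdc25b, Gtse1, Odc1, Tfap4 and Wdr12, which with Mcm2 had the smallest blocked p of these lists, had blocked adjusted p-values of 0.166 to 0.425, and Odc1 was higher with desIgf1 and the others lower.

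With 1 library left out, the medians of the 12 lists past camera kept their sign and ran from 0.41 to 0.79 for cholesterol synthesis, 0.13 to 0.38 for fatty acid synthesis, 0.17 to 0.52 for hypoxia, 0.01 to 0.33 for glycolysis, 0.23 to 0.77 for chemokines, 0.24 to 0.49 for mitochondrial transcripts, 0.04 to 0.39 for interferon response, -0.33 to -0.05 for naive and memory genes, -0.50 to -0.14 for S phase, -0.41 to -0.04 for G2 and M phase, -0.50 to -0.19 for ribosome biogenesis and -0.21 to -0.09 for apoptosis genes.

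**Figure D3:**
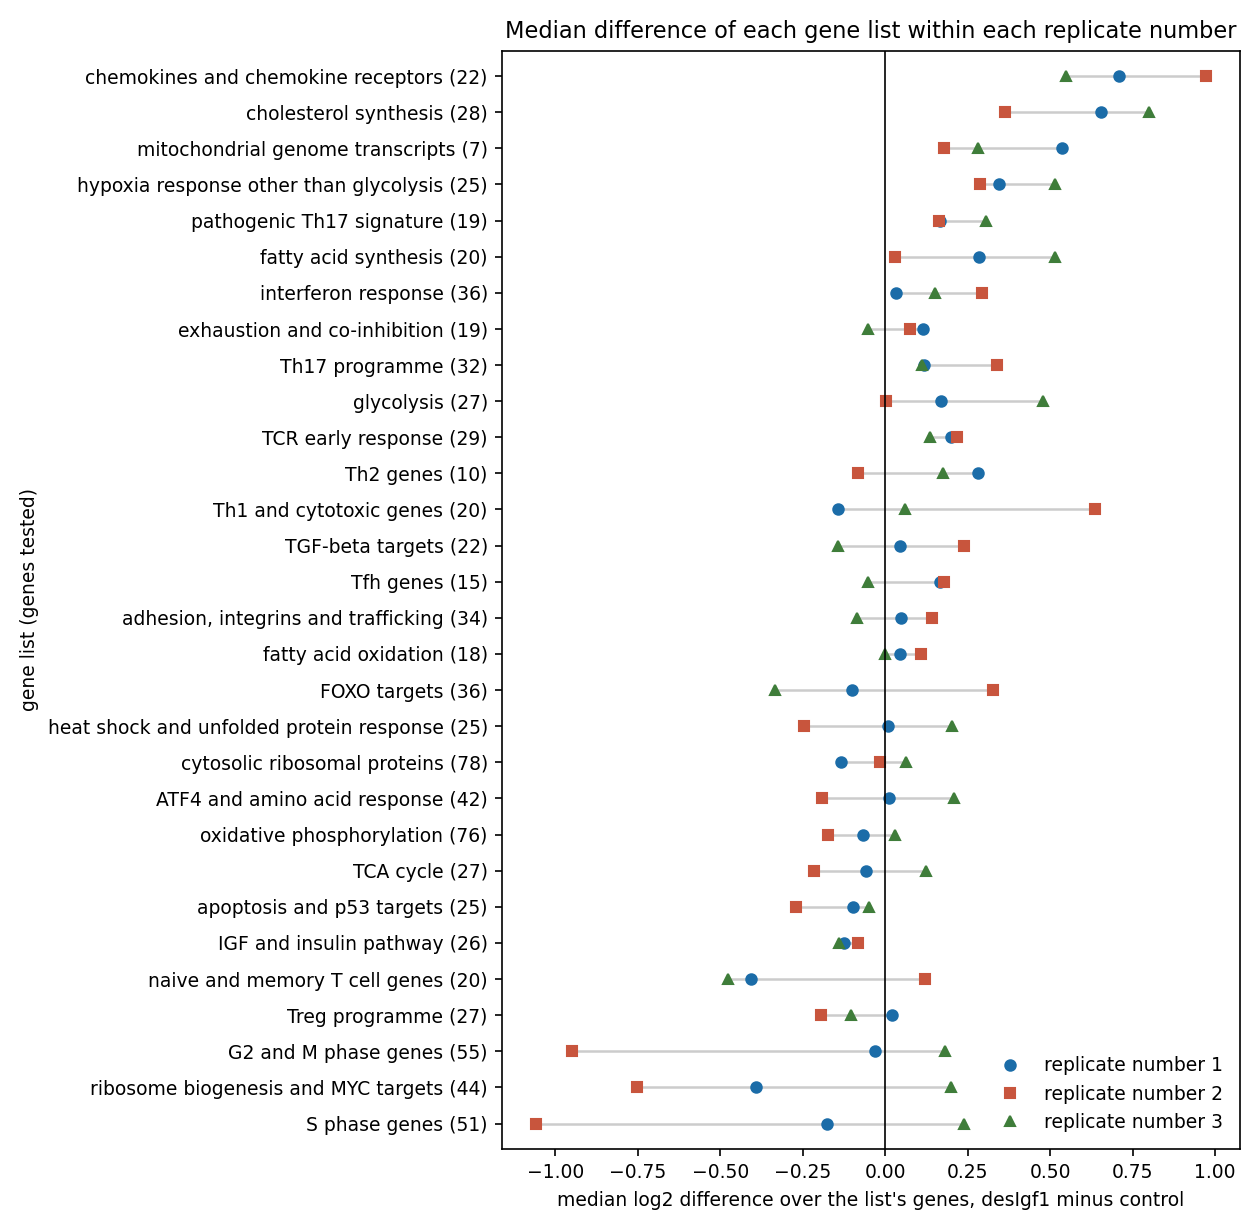
Median log2 difference between the desIgf1 and the control library of each replicate number, over the tested genes of each of 30 lists, with 1 point per number. Cholesterol synthesis is above 0 in all 3 pairs (0.65, 0.36 and 0.80), and S phase genes lie on both sides (-0.18, -1.06 and 0.24).

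Of the other lists, 3 passed camera with the preset correlation. Transcripts of the mitochondrial genome were higher (median 0.34 over 7 genes, adjusted p = 0.00193), but adjusted p = 0.732 with an estimated correlation, and 0.0864 with the block without the libraries numbered 1. mt-Co1 was at 2633 ± 374 and 4160 ± 1138 CPM, mt-Nd1 at 1183 ± 252 and 1590 ± 251 CPM, and mt-Nd4 and mt-Nd5 were also higher in all 3 pairs, with blocked adjusted p-values of 0.189 to 0.272. With adjustment over those 7 genes alone, 5 were higher with the block and 0 without it. Mitochondrial transcripts took 1.36, 1.42 and 1.103% of the counts in desIgf1 libraries 1 to 3 and 0.836, 1.12 and 0.899% in controls 1 to 3. Nuclear genes of oxidative phosphorylation did not pass (median -0.06 over 76 genes, adjusted p = 0.0958). Interferon response genes were higher (median 0.19 over 36 genes, adjusted p = 0.0214), but adjusted p = 0.732 with an estimated correlation. The call ended without control library 3 (median 0.04, adjusted p = 0.210) or desIgf1 library 1 (0.12, 0.129), and with the block without the libraries numbered 3 (adjusted p = 0.198). Their smallest blocked p-values went both ways, with Gbp2 at 406 ± 280 and 104 ± 32.4 CPM, Gbp3 at 33.5 ± 14.5 and 17.6 ± 4.09 CPM and Slfn8 at 13.8 ± 1.69 and 20.9 ± 1.31 CPM, and Isg15 at 1.14 ± 0.180 and 2.04 ± 0.898 CPM. Apoptosis and p53 target genes were lower (median -0.09 over 25 genes, adjusted p = 0.0298), but adjusted p = 0.732 with an estimated correlation. Leaving out control library 1 or 3 or desIgf1 library 2 ended the call (adjusted p = 0.0949, 0.0794 and 0.0525), as did leaving out the libraries numbered 2 with the block (0.120). Bcl2l11, Aen and Phlda3 had blocked adjusted p-values of 0.156 to 0.179, and Cdkn1a was at 55.8 ± 26.6 and 46.7 ± 14.7 CPM. TCR early response (adjusted p = 0.119), fatty acid oxidation and the TCA cycle (both 0.427), cytosolic ribosomal proteins (0.364), heat shock and unfolded protein response (0.940) and ATF4 targets (0.943) did not pass.

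The cultures had held irradiated splenocytes, and the sorted cells held some of their marker transcripts. T cell markers summed to 8866 ± 368 CPM with desIgf1 and 8552 ± 392 CPM in controls (two-sided exact permutation p = 0.2). B and plasma cell markers summed to 86.4 ± 23.5 CPM with desIgf1 and 117 ± 59.8 CPM in controls, most of it Ighm, while Cd79a was below 0.5 CPM in all 6 libraries. Macrophage and monocyte markers summed to 176 ± 16.1 and 151 ± 46.9 CPM, most of it Ctss, and neutrophil markers summed to 2.13 ± 0.503 and 1.55 ± 0.521 CPM. Dendritic cell markers were the only list with no overlap between the groups, at 218 ± 40.8 and 158 ± 21.3 CPM (exact permutation p = 0.1, the smallest that 3 libraries against 3 allow, and 0.55 adjusted over 11 lists). H2-Ab1 was the most abundant of them at 68.7 CPM, and Ccl22 and Irf8 are also expressed by activated T cells. The remaining lists had exact permutation p-values from 0.2 to 0.8, namely CD8 T cells (0.3), B and plasma cells (0.6), macrophages and monocytes (0.5), neutrophils (0.2), NK cells (0.8), gamma delta T cells (0.2), erythroid cells and platelets (0.3), stroma and endothelium (0.4) and mast cells and basophils (0.8).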

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

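The comparisons of settings that combine the block with another choice were chosen after the data were examined. edgeR called 0 genes with median-of-ratios or upper-quartile factors, with the stricter filter, with protein-coding genes only, and limma voom called 0. Without a low-count filter it called 16 (13 at least 2-fold), with the replicate block 44 (37), and DESeq2 called 202 (107). Combined with the block, DESeq2 called 606 (237), limma voom 37 (32), no filter 281 (148), thinned libraries 63 (52), the stricter filter 27 (25), protein-coding genes 21 (19) and the GC and length correction 11 (11). The cause was not tested, except that the filters change the number of genes tested, 11528 to 22504. In these fits of the same libraries, all 44 genes called with the block kept their direction wherever tested, except 1 without desIgf1 library 3. With libraries left out the counts ran from 0 to 1069 (0 to 459 at least 2-fold). Each single library left out gave 0, and the higher counts came from the blocked fit without both libraries of a number. Lists past camera went from 12 to 0 with an estimated correlation, with the block or without it, to 1 with fry, 0 with fry and the block, 4 with the mixed fry test (Th17 programme, pathogenic Th17 signature, Tfh genes and chemokines) and 19 with it and the block. Camera called the pathogenic Th17 signature higher without control library 1 (adjusted p = 0.0419) and, with the block, without both libraries of number 1 (0.0136) or 2 (0.0378). It called TCR early response higher with the stricter filter (0.0287) and without control library 1 (0.00793), desIgf1 library 2 (0.0165) or 3 (0.0310), and Th1 and cytotoxic genes with the stricter filter (0.0409, and 0.0151 with the block) and without control library 1 (0.0419). Leaving libraries out or changing the filter also brought calls of FOXO targets, oxidative phosphorylation, the IGF and insulin pathway, ribosomal proteins and, in the blocked fit, TGF-β targets. With libraries left out they ran from 8, without control library 3, to 14. With libraries left out, the median of S phase genes ran from -0.62 to -0.00219 and that of G2 and M phase genes from -0.49 to 0.0773, the upper ends without both number 2 libraries, where camera put both lists on the higher side without a call (adjusted p = 0.855 and 0.175). ATF4 targets, not called with all libraries, ran from -0.10 to 0.0846, were past the mixed fry test with the block (median -0.0342, adjusted p = 0.0217), and were called higher by camera without control library 2 (0.06, adjusted p = 0.0372) and without both number 2 libraries (0.0846, adjusted p = 0.0282). Marker lists with no overlap between groups went from 1 to 7 with a library left out, 7 without control library 3. Over the single lists, 82 comparisons with another setting lost a call, 42 gained one, 192 kept one, 369 had none in either and 5 turned direction. Over the 87 named genes tested, none of them called in the main fit, 451 comparisons gained a call and 1631 did not. Apart from the genes and the IGF and insulin list named above, the block changed no call of a list in camera, and with directional fry it lost the chemokine list (adjusted p = 0.105). Depth does not limit genes such as Aldoc, but Ifng, with at most 28 counts, could not be tested.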

Other observations

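Tests of splenocyte RNA and of sex against the first component were chosen after the result was seen. Kit, Itgae, Ccr6 and Penk were highest in the number 3 libraries of both groups. Kit, the stem cell factor receptor, was at 24.2, 46.4 and 118 CPM in desIgf1 libraries 1 to 3 and at 6.51, 3.66 and 145 CPM in controls 1 to 3. Itgae, the integrin of intraepithelial T cells, was at 8.91, 5.11 and 48.4 CPM and at 1.38, 0.680 and 54.7 CPM. Ccr6, a chemokine receptor typical of Th17 cells, was at 29.8, 46.2 and 153 CPM and at 12.1, 16.1 and 148 CPM. Penk was at 2.25, 3.28 and 114 CPM and at 0.504, 0.446 and 93.8 CPM. In numbers 1 and 2 these genes were higher with desIgf1, and in number 3 the 2 libraries were close together. These genes were picked after their values were seen, and none passed either edgeR test.

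The Treg programme went both ways, with 8 genes higher and 10 lower in all 3 pairs (camera adjusted p = 0.376). Lrrc32, which encodes the TGF-β-presenting protein GARP, was at 39.6 ± 20.3 CPM in controls and 6.56 ± 1.37 with desIgf1 (SD, n = 3, edgeR adjusted p = 0.170, and 0.0807 with the block). Il10 was at 1.83 ± 0.534 and 0.726 ± 0.287 CPM (adjusted p = 0.489, blocked 0.185). Csf2, the gene of GM-CSF, was near the floor but higher in all 3 pairs, with a log2 fold change of 1.84 ± 0.39 (adjusted p = 0.316, blocked 0.109). These were also picked after their values were seen.

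Glycolysis, hypoxia and cholesterol genes were higher with desIgf1 in the blocked fit, with a median log2 fold change of 0.38 over 80 genes, 53 of them higher in all 3 pairs. Glycolysis alone had a smaller blocked median, 0.15, with a median difference of 0.00307 in number 2. Of its 27 genes 12 were higher in all 3 pairs, against 21 of 28 cholesterol and 20 of 25 hypoxia genes. A GC or length trend predicts that a correction removes the rise of the 80 genes, and with it their median was 0.37. Of 8 called genes among the 80, 3 stayed called (adjusted p at most 0.0675), while the median absolute log2 fold change of the 8 went from 1.02 to 0.94 and its standard error from 0.0914 to 0.0846, and fewer genes had an unadjusted p under 0.05 (1750 against 1982), which raises adjusted values. Thinning to the smallest total left a median of 0.38, but it keeps the proportions of each library and so tests only effects of low counts. The desIgf1 library had the smaller total in number 1 and the larger in number 3. Medians of all 3 lists were above 0 in both, which argues against depth as the only cause. Cells added with RNA of these 80 genes alone would need a share of at least 0.237% (summed rise 3287 ± 918 CPM, SE over pairs, less 1 SE). At that share, 2 or more abundant transcripts of each cell type could stand at no more than the levels below, with 1 SE added to their rise. The levels were 90.9 CPM for B cells (Cd79a, Cd79b, Igkc, Ighm) and 6.76 CPM for neutrophils (S100a8, S100a9). They were 109 CPM for macrophages (Lyz2, Ctss, Tyrobp, Fcer1g) and 79.4 CPM for dendritic cells (Cd74, H2-Aa, H2-Ab1, H2-Eb1). This argues against RNA of B cells and neutrophils, as does the sort on the Il17a reporter. Macrophages and dendritic cells are not settled by these levels. The 10 tested dendritic cell markers had a median of 0.49 (bootstrap SE 0.176, markers resampled), above the 0.38 of the lists. Cd74 and H2-Ab1 were higher and could stand at 7974 and 10131 CPM, but H2-Aa and H2-Eb1 were lower (log2 -0.27 and -0.48). The 13 macrophage markers had a median of 0.31 (bootstrap SE 0.160, markers resampled), with Ctss alone of the 4 abundant ones free to stand higher than 980 CPM. Tyrobp and Fcer1g, on which the macrophage level rests, were added after values were seen. Resampling markers does not measure the spread between libraries. A response to desIgf1 stays open, as a hypothesis, as do differences between cultures in density or oxygen, which no label records.

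The block turned 0 called genes into 44, and a candidate explanation is that libraries with the same number share animals or a culture day. Of the 6 ways to match desIgf1 with control libraries, the matching by number called 44, the one that exchanges control numbers 1 and 2 called 32, and the other 4 called 0. Only matchings that join the number 3 libraries with each other called genes, and whether the 32 are among the 44 was not checked. Sex alone is opposed, since a fit with sex as the only covariate called 0 genes, though both libraries of number 1 held Xist. What the numbers share is not given by a label.

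The first principal component set the number 3 libraries apart with a gap of 46.9, and after thinning to equal totals the gap was 46.0. Thinning keeps the proportions of each library and so tests only effects of low counts. The number 3 libraries had the largest and the smallest total, 47929948 with desIgf1 and 34567899 in the control. Both lay on the same side, which argues against depth. Sex does not separate them either, because the means of numbers 1 and 2 lay 1.45 apart and those of numbers 2 and 3 lay 66.4 apart, although numbers 2 and 3 are both male. A difference in animals, day or culture may lie behind it and was not tested beyond these values.

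The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For edgeR without the block all 10 splits gave as many genes as the real one, 0 against a highest other of 0, and the same held for 2-fold changes. The real split called 12 lists and the highest other 14, with 4 splits at 12 or more. DESeq2 called 202 genes in the real split and 255 in the highest other, with 2 splits at 202 or more. That other split set desIgf1 library 1 and control libraries 1 and 2 against the rest, and it parts 1 pair. Among the 4 splits that part all 3 pairs, DESeq2 called 202 in the real one and at most 2 in the others. For edgeR with the block, 1 of these 4 splits reached 44, the real one, and the highest other was 0.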
